A study of Homo sapiens with 57 samples.

How the data were processed

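RNA abundance was measured in MCF-7 cells, an established human breast cancer line, after serum starvation and treatment with epidermal growth factor (EGF) or heregulin (HRG). Each ligand was given at 4 doses (0.1, 0.5, 1 and 10 nM) and sampled at 7 times (5, 10, 15, 30, 45, 60 and 90 min), with 1 array per condition. The data held 28 HRG arrays, 27 EGF arrays and 1 untreated array per ligand, 57 in all. The EGF 10 nM condition at 60 min was not analysed here, and detection calls were not used here.

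The values deposited were the signal intensity of each of 22277 probe sets on a linear scale, between 0.1 and 32343. The submitters' processing notes name GCOS, the Affymetrix operating software, which summarises the probes of a probe set into 1 intensity; its version and settings are not given in the sources used here. The trimmed mean of the intensities, with 2% left out at each end, lay between 500.126 and 500.155 in every array, so that the arrays had been scaled by the authors to a common target of 500. The median signal of an array lay between 106.8 and 143. Such scaling removes any change in total RNA per cell, and it fixes the mean of an array without making the distributions alike. For arrays, the number of arrays limits the precision of each estimate.

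Arrays were rescaled to the trimmed mean of 500 and analysed as log2 of the signal plus an offset of 32, which damps noise near the background and makes the fitted fold of a weakly expressed gene smaller than the fold of its raw signal. Of the probe sets, 19064 carried 1 gene symbol, 1043 several and 2108 none, and 62 were controls. Probe sets with 1 symbol were reduced to 11963 genes by keeping for each gene the probe set with the highest mean. A gene was tested when its signal was above the median of the array in at least 4 arrays, which left 7269 genes. Positions in the genome were not used.

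A linear model was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). It held 14 means, 1 per ligand and time, 2 means for the untreated arrays, and for each ligand a slope on the centred log10 dose in each of 3 phases: early (5 and 10 min), middle (15 and 30 min) and late (45, 60 and 90 min). These 22 coefficients left 35 residual degrees of freedom, and the median residual SD was 0.158 on the log2 scale. All tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. "Rose", "fell" and "passed" refer to that threshold. Contrasts compared the late with the early arrays of each ligand, each of 5 later times with the early arrays, the changes of the 2 ligands, the dose slopes, the late arrays with the untreated array, and the 2 ligands at 5 and 10 min.

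The genes named were chosen by rank of the absolute log2 value among those past the threshold: for late against early, the 14 largest rises and 8 largest falls per ligand; for the difference between the ligands in the late change, the 10 largest in each direction; for the late dose slopes, 8 positive and 4 negative per ligand; and for the difference in slope, 4 in each direction. From each gene list, up to 4 members with the largest absolute change were taken, and any member needed to explain a count. These rules, the groups, the contrasts, the gene lists and the planned settings were fixed before the data were examined.

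There were 22 gene lists: immediate early transcription factors, ERK pathway feedback inhibitors, RNA decay and antiproliferative early genes, secreted ligands and cytokines, cytoskeleton, adhesion and invasion genes induced by serum, ErbB receptors and adaptors, estrogen receptor targets, quiescence and FOXO targets, G1/S genes, G2/M genes, NF-kappaB targets, CREB and cAMP early genes, heat shock genes, ATF4 and unfolded protein response genes, sterol synthesis genes, hypoxia genes, housekeeping genes, short-lived transcription regulators, luminal and differentiation markers, and markers of fibroblasts, leukocytes and endothelial cells. Some genes stand in more than 1 list. Each list was tested against the other genes with camera in limma, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data, and adjusted over the lists of a contrast. Passing members were counted over all genes tested and adjusted over the list alone.

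A score per array, for the immediate early factors and for the ERK feedback inhibitors, was the mean over the list of the log2 difference from the mean of the early arrays of the same ligand. The scores of the 2 ligands were compared over 11 pairs of late arrays matched by dose and time, with an exact sign-flip test over the 2048 sign patterns. Their slope on log10 dose was tested by a permutation test with 100000 draws, shuffling doses within each time; there were 13824 arrangements for HRG and 3456 for EGF. The slope was also taken from the pairs of doses that shared time and scan day, with an exact test over the swaps within pairs.

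The instrument records gave 6 scan days, here called A to F. The HRG arrays at 0.1 and 0.5 nM were scanned on day B (14 arrays), those at 1 and 10 nM on day C (14), the EGF arrays at 0.1 and 0.5 nM on day D (14), and those at 1 and 10 nM on day E (12), except that the EGF 10 nM array at 30 min shared day F with the untreated EGF array. The untreated HRG array was scanned alone on day A. The ligands shared no scan day, so that day and ligand cannot be told apart in a direct comparison of levels; the late change was therefore also computed within each day, and all contrasts with scan day as a block.

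The alternative settings fixed in advance were quantile normalization, offsets of 1 and 128, no filter and a filter at 29 arrays, all probe sets, no _x_at and _s_at probe sets, eBayes robust and without trend, array weights, dose as a factor and as a rank, each ligand alone, 5 min as the baseline, 30 to 90 min as late, 90 min left out, scan day as a block, each dose and each array left out, the list median in place of the mean for the scores, and the estimated correlation. Groups were also redrawn at random, 100 times per comparison with the real grouping included. On simulated data of 7269 genes, the HRG late change recovered 92.5% of 80 log2 changes of 0.5 and 100% of 80 of 1. Of 205 calls 11 were false. The HRG late dose slope recovered 61.3% of 80 slopes of 0.25 and 92.5% of 80 of 0.5, with 7 of 170 calls false. Unchanged EGF arrays gave 0 calls. These rates hold for the simulated data only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.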

Results

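MCF-7 cells, a breast cancer line that expresses the estrogen receptor, were starved of serum and then exposed to EGF, a ligand of the EGF receptor, or to HRG, a ligand of ErbB3 and ErbB4. RNA was measured on 57 Affymetrix human expression arrays: 27 after EGF, 28 after HRG and 1 untreated array for each ligand. The series asked how transcription in the first 90 min depends on which ErbB ligand is given and at what dose. Arrays at 45, 60 and 90 min are called late (11 for EGF, 12 for HRG) and those at 5 and 10 min early (8 for each ligand). No condition had a replicate, so p-values rest on the spread of single arrays around the model, which may be technical only, and the ± given after a log2 value is its SE. The median signal ran from 106.8 to 143 per array. The log2 ratio of the 3' to the 5' actin probe sets, a measure of RNA quality, was 0.898 ± 0.284 (SD, n = 28) in the HRG arrays and 0.347 ± 0.158 (SD, n = 27) in the EGF arrays, and 1.52 and 0.79 in their untreated arrays. Markers of other cell types mostly fell below the expression filter: 2 of 12 fibroblast, 1 of 13 leukocyte and 0 of 8 endothelial markers were expressed enough to be tested, too few for a test of these lists.

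The first comparison asked which genes EGF changed between the early and the late arrays. Late EGF arrays held more RNA of the immediate early genes, which serum and growth factors induce without new protein synthesis. NR4A1, an orphan nuclear receptor, rose by 2.01 ± 0.24 on the log2 scale (adjusted p = 1.1e-07), and the zinc finger transcription factors EGR3 and EGR4 by 1.97 ± 0.14 (1.2e-13) and 1.85 ± 0.19 (1.7e-09). The nuclear receptor NR4A3 rose by 1.32 ± 0.23 (adjusted p = 0.00022), the matricellular protein gene CCN2 by 1.13 ± 0.14 (1.1e-07) and FOS, a subunit of the AP-1 transcription factor, by 1.07 ± 0.16 (6.4e-06). MAFF (1.12 ± 0.12), KLF10 (1.06 ± 0.08), CCN1 (0.96 ± 0.12), EGR1 (0.94 ± 0.11), IER2 (0.93 ± 0.08), ID1 (0.92 ± 0.10), the phosphatase gene DUSP2 (0.91 ± 0.11) and PHLDA1 (0.89 ± 0.12) completed the 14 largest rises, with adjusted p from 1.9e-11 to 2.1e-06 except KLF10 at 1.2e-13. The falls were smaller. The cell surface glycoproteins CEACAM6 and CEACAM5 changed by −0.62 ± 0.11 (adjusted p = 0.00026) and −0.61 ± 0.12 (0.00081), and the ribonuclease RNASE1 by −0.53 ± 0.13 (0.0066). The protease inhibitor SERPINA3 changed by −0.53 ± 0.06 (adjusted p = 1.3e-07) and PIK3IP1, an inhibitor of PI3 kinase, by −0.52 ± 0.08 (2.6e-05). PLAT, tissue plasminogen activator, changed by −0.50 ± 0.14 (0.021), and OASL and OAS1, both induced by interferon, by −0.48 ± 0.12 (0.013) and −0.47 ± 0.11 (0.0053). In all, 379 of 7269 genes passed, 232 higher and 147 lower in the late arrays.

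The size of these EGF changes differed between doses. The count was 97 without the 10 nM arrays, 97 without 0.1 nM and 89 without 0.5 nM. The late change of EGR4 was 0.30 at 0.1 nM and 4.54 at 10 nM, that of NR4A3 0.15 and 3.64, and that of CCN2 0.42 and 2.57. EGR1 moved by 0.96 and 0.89 at these doses. CEACAM6 moved by −0.12 at 0.1 nM and −1.60 at 10 nM, CEACAM5 by −0.13 and −1.35, and SERPINA3 by −0.23 and −1.02. These 3 genes already rose with dose at 5 and 10 min, with slopes of 0.77, 0.79 and 0.47 per factor of 10. Their late slopes of −0.03, 0.13 and 0.04 did not pass, so that the larger falls at 10 nM went with a higher start. Within scan day D (0.1 and 0.5 nM) 417 genes passed (232 higher, 185 lower). Within day E (1 and 10 nM) 48 passed (42 higher, 6 lower). All 379 were called from both days, so their same sign on each is no replication. Day D alone did not pass NR4A3 (0.45, adjusted p = 0.24), CCN2 (0.45, 0.067), FOS (0.69, 0.059), CEACAM6 (−0.13, 0.71), CEACAM5 (−0.25, 0.50), SERPINA3 (−0.27, 0.12), PLAT (−0.15, 0.68), RNASE1 (−0.39, 0.24) or OAS1 (−0.44, 0.075). Day E alone did not pass EGR1 (0.85, adjusted p = 0.083), RNASE1 (−0.68, 0.15), PIK3IP1 (−0.46, 0.15), OASL (−0.30, 0.50) or OAS1 (−0.45, 0.44). The actin ratio was alike in both phases, 0.312 ± 0.168 early (SD, n = 8) and 0.342 ± 0.0932 late (SD, n = 11). It differed across doses, at 0.455 to 0.841 in the 6 arrays at 10 nM and 0.1 to 0.431 at lower doses. With it as a covariate, tried after the values were seen, 465 genes passed (277 higher, 188 lower). The EGR4 call was lost with an offset of 1 (0.61, adjusted p = 0.30) and the NR4A1 call without probe sets of lower specificity (0.31, 0.40). Other probe sets read 0.12 for CEACAM5, 0.49 for EGR4, and 0.99 and 0.03 for NR4A3. Dose as a factor (−0.48, adjusted p = 0.055) and 5 min as the baseline (−0.58, 0.067) lost PLAT, and the last also lost RNASE1 (−0.52, 0.076), OASL (−0.46, 0.11) and OAS1 (−0.41, 0.12). PLAT was also lost with each ligand fitted alone, and OASL with 30 to 90 min as late (−0.36, adjusted p = 0.068) and with 90 min left out (−0.48, 0.055).

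By gene group, EGF raised 18 of 27 immediate early transcription factors and lowered none, and 23 rose when adjusted over the list alone. The list median was 0.62 (adjusted p = 1.1e-42), and JUNB rose by 0.87 ± 0.10 and MYC by 0.51 ± 0.09. Of 12 ERK pathway feedback inhibitors, 4 rose, or 8 adjusted over the list alone, with a median of 0.29 (adjusted p = 1.8e-07). The 4 were the dual specificity phosphatase genes DUSP2, DUSP5 (0.74 ± 0.10) and DUSP4 (0.55 ± 0.12), and SPRED2 (0.31 ± 0.08). Of 13 RNA decay and antiproliferative early genes, 5 rose, or 6 adjusted over the list alone, with a median of 0.13 (adjusted p = 3.2e-08). Among these the pseudokinase gene TRIB1 rose by 0.73 ± 0.09 and ZFP36, whose product binds AU-rich mRNAs, by 0.65 ± 0.10. Of 11 secreted ligands and cytokines, 5 rose, and 5 rose and 1 fell adjusted over the list alone, with a median of 0.17 (adjusted p = 1e-05). HBEGF, itself an EGF receptor ligand, rose by 0.76 ± 0.16 and endothelin, EDN1, by 0.59 ± 0.10. Of 9 CREB and cAMP early genes, 4 rose, or 7 adjusted over the list alone, with a median of 0.37 (adjusted p = 4.3e-08) and the kinase gene SIK1 at 0.52 ± 0.08. Of 17 short-lived transcription regulators, 6 rose, and 6 adjusted over the list alone, with a median of 0.21 (adjusted p = 1.5e-07). Among 16 G2/M genes, 0 passed over all genes and 0 adjusted over the list alone. Their median of 0.09 had an adjusted p = 0.024, and adjusted p = 0.300 with an estimated correlation. The remaining lists did not pass, with adjusted p from 0.057 to 0.99. The cytoskeleton, adhesion and invasion list had 3 of 15 members up, PHLDA1, PHLDA2 (0.45 ± 0.10) and RHOB (0.20 ± 0.04), and 4 up and 1 down adjusted over the list alone. Its median was −0.01, beside a mean of 0.08 and a test pointing up (adjusted p = 0.21). For the ATF4 list the median of −0.03 and mean of −0.01 also lay opposite to the direction of its test (adjusted p = 0.99). The hypoxia genes had a median of −0.03 beside a mean of 0.01 and a test pointing up (adjusted p = 0.80).

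The same comparison for HRG gave larger changes in more genes. EGR4 rose by 5.42 ± 0.18 (adjusted p = 8.7e-27) and NR4A3 by 5.37 ± 0.23 (2.7e-23). Over the 4 doses the rises were 4.41 to 5.96 and 3.19 to 6.82. Their early HRG log2 levels with the offset of 32, 5.91 and 5.47, lay near it, so the size of these rises depended on it. Over all settings this size ran from 4.07 to 5.79 for EGR4 and 3.81 to 7.22 for NR4A3. Other probe sets read 3.57 for EGR4 and 3.83 and 0.16 for NR4A3. NR4A1 rose by 3.81 ± 0.23 (adjusted p = 1.2e-17), the AP-1 subunit gene FOSB by 3.38 ± 0.23 (1.6e-16), EGR3 by 3.28 ± 0.14 (3.3e-23), MAFF by 3.21 ± 0.12 (2e-25) and GEM, a small GTPase, by 3.01 ± 0.15 (4.3e-21). CCN2 (2.57 ± 0.13), the stress-responsive transcription factor ATF3 (2.56 ± 0.12), TRIB1 (2.44 ± 0.09), PHLDA1 (2.28 ± 0.12), the AP-1 subunit gene FOSL1 (2.27 ± 0.17), CCN1 (2.21 ± 0.12) and ARC (2.07 ± 0.20) completed the 14 largest rises, with adjusted p of 1.8e-11 or less. Among the falls, H1-6, a testis-type linker histone, changed by −1.0 ± 0.14 (adjusted p = 3.5e-07), PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1, by −0.98 ± 0.07 (8.8e-15) and MICOS10P1, annotated as a pseudogene, by −0.78 ± 0.11 (3.1e-07). PCDHGA8, a protocadherin, changed by −0.72 ± 0.13 (6.5e-05), ZNF362 by −0.71 ± 0.13 (9.6e-05), the cytokine IL1A by −0.71 ± 0.15 (0.00051), the semaphorin SEMA3D by −0.69 ± 0.13 (9.4e-05) and TCHH, trichohyalin, by −0.69 ± 0.09 (2.7e-08). In all, 1167 genes passed, 587 higher and 580 lower in late arrays (636 and 710 with scan day as a block). Day B gave 536 (332 higher, 204 lower) and day C 845 (431 and 414). Of the 1167, called from both days, 1154 and 1165 had the same sign there. The actin ratio was 1.04 ± 0.411 early (SD, n = 8) and 0.834 ± 0.230 late (SD, n = 12). Day B alone did not pass ZNF362 (−0.38, adjusted p = 0.20) or SEMA3D (−0.54, 0.073), and NR4A1 did not pass without probe sets of lower specificity (0.22, 0.51), whereas another NR4A1 probe set read 1.93.

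By group, HRG raised 25 of 27 immediate early transcription factors and lowered 1, ID2, an inhibitor of basic helix-loop-helix factors, at −0.29. The same numbers passed adjusted over the list alone, and the median was 1.26 (adjusted p = 7e-66). JUNB rose by 1.56 ± 0.10 and KLF6 by 1.42 ± 0.13, and ELF3, at −0.04, did not pass. Of 12 ERK pathway feedback inhibitors, 8 rose and 1 fell, also adjusted over the list alone, with a median of 0.61 (adjusted p = 4.8e-10). DUSP5 rose by 1.96 ± 0.10, DUSP2 by 1.83 ± 0.10 and DUSP4 by 1.73 ± 0.12, while SOCS2, a suppressor of cytokine signalling, was the member that fell (−0.50, adjusted p = 1.8e-09). Of 13 RNA decay genes, 10 rose, and 10 rose and 1 fell adjusted over the list alone, with a median of 0.63 (adjusted p = 2.4e-19). ZFP36 rose by 1.84 ± 0.10 and IER3 by 1.40 ± 0.10. Of 11 secreted ligands, 7 rose and IL1A fell, also adjusted over the list alone, with a median of 1.05 (adjusted p = 1.2e-15). HBEGF rose by 1.94 ± 0.15 and EDN1 by 1.53 ± 0.09. Of 15 cytoskeleton, adhesion and invasion genes, 10 rose, or 11 adjusted over the list alone, with a median of 0.42 (adjusted p = 4.2e-14). FHL2, a LIM domain protein gene, rose by 1.51 ± 0.17, PHLDA2 by 1.26 ± 0.10 and the vinculin gene VCL by 0.79 ± 0.05. Of 9 CREB and cAMP early genes, 7 rose, and 7 adjusted over the list alone, with a median of 1.01 (adjusted p = 3e-18) and SIK1 at 1.76 ± 0.08. Of 17 short-lived regulators, 12 rose and 1 fell, also adjusted over the list alone, with a median of 0.59 (adjusted p = 1.4e-18). Of 8 heat shock genes, 4 rose, and 4 adjusted over the list alone, with a median of 0.15 (adjusted p = 0.0017). The co-chaperone gene DNAJB1 rose by 0.81 ± 0.05 and HSPH1 by 0.35 ± 0.07.

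Genes of starved, resting cells and hypoxia genes gave less certain calls after HRG. Of 16 quiescence and FOXO targets, 8 fell and 3 rose, or 9 and 3 adjusted over the list alone. Their median of −0.18 had an adjusted p = 0.033, and adjusted p = 0.094 with an estimated correlation. TXNIP, whose product inhibits glucose uptake, changed by −0.63 ± 0.07 and PIK3IP1 by −0.45 ± 0.08, whereas the insulin receptor substrate gene IRS2 and the growth arrest gene GADD45A were 0.55 ± 0.06 and 0.93 ± 0.09 higher. Of 9 hypoxia genes, 3 rose, and 3 adjusted over the list alone. Their median of 0.06 had an adjusted p = 0.011, and adjusted p = 0.060 with an estimated correlation. The 3 were the peptide hormone gene ADM (0.73 ± 0.09), EGLN3 (0.54 ± 0.09) and VEGFA (0.48 ± 0.05). ErbB receptors and adaptors did not pass as a list, with a median of −0.01 (adjusted p = 0.51). Of their 16 members, 1 rose and 3 fell, also adjusted over the list alone. The receptor genes ERBB3 and ERBB4 changed by −0.30 ± 0.08 (adjusted p = 0.0031) and −0.29 ± 0.04 (7.1e-07), PIK3R1 by −0.26 ± 0.08 (0.017) and the adaptor gene SHC1 by 0.20 ± 0.05 (0.0019). Of 18 estrogen receptor targets, 2 rose and 3 fell, also adjusted over the list alone, with a median of −0.06 (adjusted p = 0.44). RARA, a retinoic acid receptor gene, rose by 0.52 ± 0.10 and the transcription factor gene MYB changed by −0.32 ± 0.07. ATF4 and unfolded protein response genes went both ways, with 5 up and 3 down of 13, also adjusted over the list alone, and a median of 0.09 (adjusted p = 0.090). CEBPB rose by 0.54 ± 0.04 and the mTOR inhibitor gene DDIT4 changed by −0.61 ± 0.08. The G1/S list had 3 of 13 up, also adjusted over the list alone, among them cyclin E, CCNE1, at 0.60 ± 0.09, and a median of 0.00 (adjusted p = 0.074). The G2/M list had 1 of 16 down, CENPF at −0.33 ± 0.06, also adjusted over the list alone, and a median of −0.08 (adjusted p = 0.090). The NF-kappaB list had 2 of 7 up and 1 down, also adjusted over the list alone, and a median of 0.10 (adjusted p = 0.085). Sterol synthesis genes had 1 of 10 up, IDI1 at 0.36 ± 0.05, and 1 up and 1 down adjusted over the list alone, with a median of 0.04 (adjusted p = 0.30). Housekeeping genes had 2 of 11 down, GUSB at −0.23 ± 0.05 and B2M at −0.11 ± 0.04, also adjusted over the list alone, with a median of −0.03 (adjusted p = 0.51). Luminal and differentiation markers had 0 of 10, also adjusted over the list alone, with a median of −0.05 (adjusted p = 0.53). Over all 6 contrasts tested with lists, 50 of 114 list tests passed with the preset correlation and 40 with an estimated one. The 10 that were lost are those given with such a p.

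The time points were then taken singly, each against the early arrays of the same ligand, to see when genes changed. With EGF, 1 gene passed at 15 min, MYC (0.61 ± 0.12, adjusted p = 0.0427; named after its value was seen), 16 at 30 min, 48 at 45 min, 51 at 60 min and 160 at 90 min. At 15 min 434 genes lay under an unadjusted p of 0.05 with EGF. With HRG, 8 genes passed at 15 min, among them EGR4, NR4A1, EGR3, FOS and IER2, 79 at 30 min, 326 at 45 min, 524 at 60 min and 1120 at 90 min. With HRG 73 rose and 6 fell at 30 min, while 563 rose and 557 fell at 90 min. This last balance turned in several settings, as 604 up and 658 down with scan day as a block and 602 and 671 with dose as a factor. FOS was transient, with a mean change over doses of 2.34 ± 0.25 at 30 min and −0.03 ± 0.49 at 90 min with HRG (SD, n = 4), and 1.60 ± 1.09 and 0.47 ± 0.52 with EGF. NR4A3, in contrast, stood at −0.11 ± 0.29 at 15 min, 3.2 ± 1.55 at 30 min and 5.66 ± 1.58 at 90 min with HRG, and PHLDA1 at 0.17, 0.47 and 3.15. The HRG fall of PPP1R3C was −0.15 at 30 min and −1.60 at 90 min, whereas IL1A reached −0.80 at 30 min and stood at −0.55 at 90 min. Single arrays weighed heavily on these counts. The 30 min EGF count was 3 without the 10 nM array at 30 min, 9 without 0.1 nM at 10 min and 10 without either 0.1 nM at 30 min or 10 nM at 5 min. The EGF count at 45 min was 17 without 10 nM and 22 without 0.1 nM at that time, and the count at 60 min was 19, 29 and 26 without 0.1, 0.5 and 1 nM at that time. At 90 min it was 82, 106 and 58 without 0.1, 1 and 10 nM at 90 min. The HRG count at 15 min was 2 without 1 nM at 15 min and 5 without 0.1 or 10 nM at 10 min. The single EGF gene at 15 min was lost or joined by others without any 1 of 38 arrays. With day as a block the EGF counts at 15, 30, 60 and 90 min were 5, 3, 85 and 249.

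**Figure D1:**
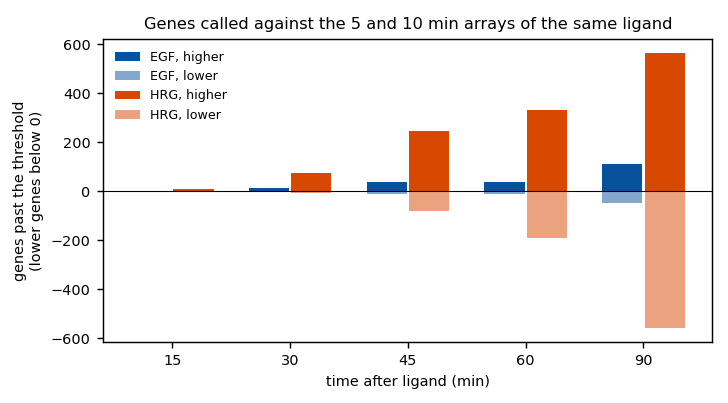
Number of genes past the threshold at each time against the 5 and 10 min arrays of the same ligand (y axis, genes; lower genes drawn below 0) by time after ligand (x axis, min), EGF in blue and HRG in orange. At 90 min the bars stand at 111 higher and 49 lower genes for EGF and at 563 and 557 for HRG.

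**Figure D2:**
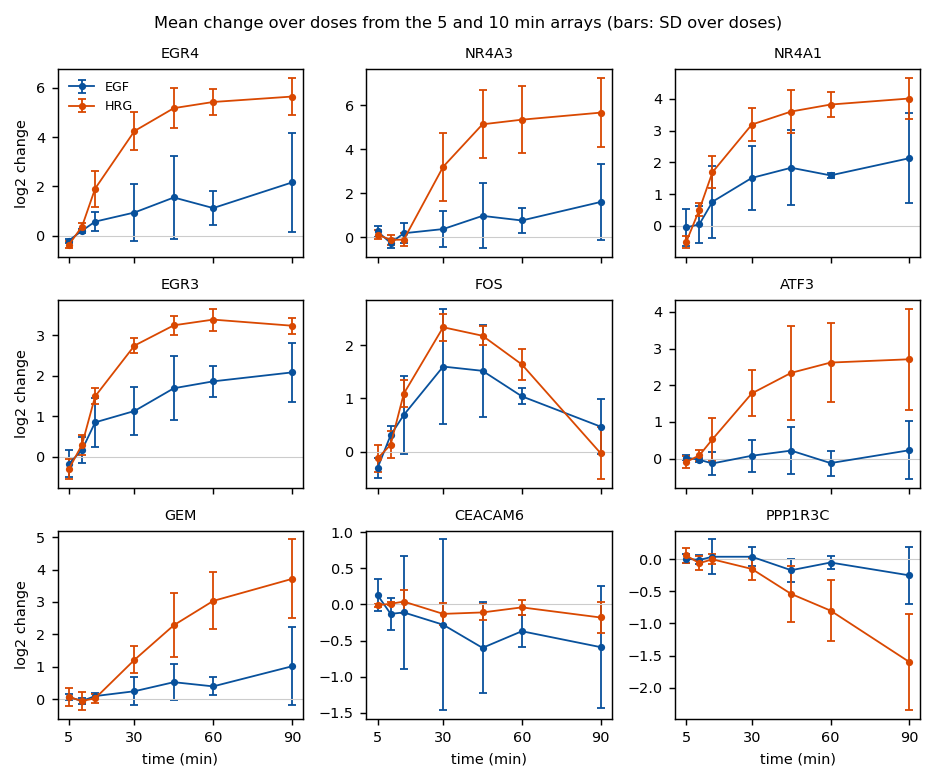
Mean log2 change from the 5 and 10 min arrays (y axis) by time after ligand (x axis, min) for 9 genes, EGF in blue and HRG in orange; points are means over the doses and bars the SD over doses (n = 4, and n = 3 for EGF at 60 min). FOS with HRG goes from 2.34 at 30 min to −0.03 at 90 min, while EGR4 with HRG stays at 4.25 to 5.65 from 30 to 90 min.

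The next comparison asked whether the ligands differed in their late change, HRG minus EGF. HRG raised most immediate early genes further than EGF. The excess was 4.05 ± 0.33 for NR4A3 (adjusted p = 1.2e-12), 3.57 ± 0.26 for EGR4 (7.3e-14), 2.76 ± 0.32 for FOSB (2.9e-08), 2.35 ± 0.17 for ATF3 (7.3e-14), 2.25 ± 0.21 for GEM (7.8e-11) and 2.09 ± 0.17 for MAFF (2.1e-12). NR4A1 (1.80 ± 0.34, adjusted p = 0.00024), TRIB1 (1.71 ± 0.13, 7.6e-14), ARC (1.56 ± 0.28, 0.00018) and FHL2 (1.52 ± 0.25, 2.5e-05) followed. FHL2 changed by 0.00 ± 0.18 with EGF. Early levels of NR4A3, EGR4, FOSB, ARC and FHL2 were near the offset with both ligands. The size and order of these differences thus depended on it. Over settings NR4A3 ran from 3.04 to 5.18, EGR4 3.05 to 3.81, FOSB 2.03 to 3.21, ARC 0.89 to 2.33 and FHL2 0.73 to 2.76. Other probe sets read 2.84 and 0.13 for NR4A3 and 3.09 for EGR4. FOS (0.19, adjusted p = 0.70), EGR1 (0.33, 0.21) and MYC (0.08, 0.78) did not pass, which does not show that they responded alike. In the other direction, PPP1R3C differed by −0.78 ± 0.11 (6.5e-07), the aminopeptidase AOPEP by −0.75 ± 0.14 (0.00023), RPAP2, an RNA polymerase II phosphatase, by −0.70 ± 0.19 (0.017), the Notch target HEY2 by −0.67 ± 0.12 (0.00013) and PCDHGA8 by −0.65 ± 0.19 (0.034). SOCS2 (−0.61 ± 0.08, 4.4e-07), the helicase gene DHX57 (−0.58 ± 0.15, 0.015), DDIT4 (−0.58 ± 0.11, 0.00033), ZKSCAN4 (−0.56 ± 0.10, 0.00019) and FRAT2, a Wnt pathway activator (−0.55 ± 0.10, 0.00013), made up the 10. DDIT4 was between −0.06 and −0.03 at every EGF dose and at −0.03, −0.69, −0.61 and −1.14 at 0.1, 0.5, 1 and 10 nM HRG. In all, 388 genes passed, 233 with the larger and 155 with the lower value for HRG, and 22, 78, 118 and 328 at 30, 45, 60 and 90 min, of which 22, 73, 91 and 203 were higher for HRG. At 45 min the count was 47 without HRG 1 nM at 45 min, and at 60 min it was 71 and 59 without EGF 0.5 and 1 nM at 60 min. The NR4A1 difference turned to −0.09 (adjusted p = 0.90) without probe sets of lower specificity. With 5 min as the baseline ARC (1.11, adjusted p = 0.063), RPAP2 (−0.64, 0.10) and DHX57 (−0.58, 0.071) were lost, and the last 2 also with 90 min left out (−0.53, 0.17 and −0.46, 0.16). PCDHGA8 was lost in 7 settings, among them without the untreated HRG array and HRG 0.1 nM at 5 min (−0.59, adjusted p = 0.077).

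**Figure D3:**
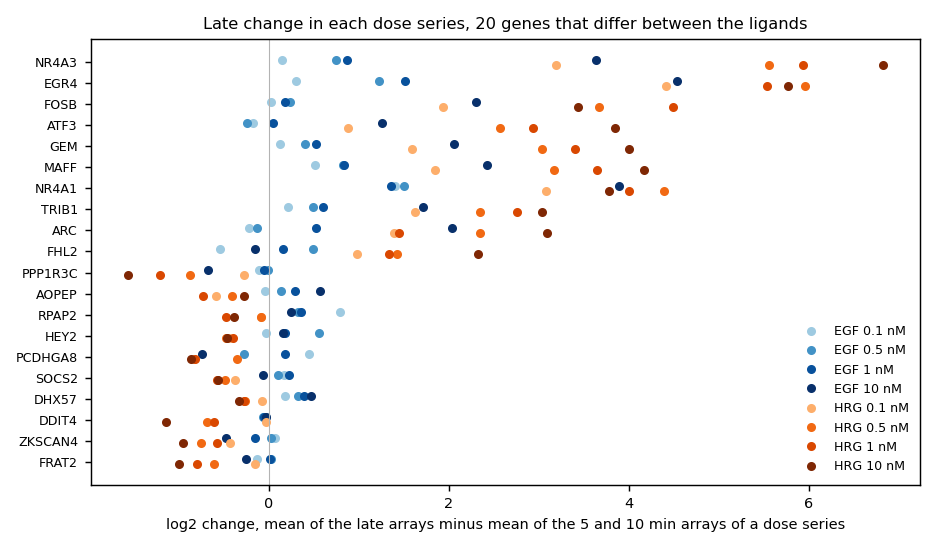
Late minus early log2 change (x axis) in each dose series for the 20 genes named for the difference between the ligands (y axis), 1 point per dose, EGF in blue and HRG in orange with darker shades for higher doses. NR4A3 lies between 0.15 and 3.64 with EGF and between 3.19 and 6.82 with HRG.

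The genes that the ligands moved overlapped. Of the 232 genes that rose with EGF, 120 (51.7%) also rose with HRG, where 18.7 were expected by chance, and of the 147 that fell, 45 (30.6%) also fell with HRG, where 11.7 were expected. Of the 120, 101 had the larger change with HRG, with a median ratio of 1.82. A pair of genes passed in opposite directions, here named after their values were seen: TDP2, a DNA repair phosphodiesterase (EGF 0.20 ± 0.04, HRG −0.12 ± 0.04), and the ubiquitin pseudogene UBBP1 (EGF −0.28 ± 0.08, HRG 0.25 ± 0.08). Across the 7269 genes, which are not independent replicates, the changes correlated with r = 0.509.

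By group, HRG exceeded EGF for 17 of 27 immediate early transcription factors and fell short for 1, ID2, or for 22 and 1 adjusted over the list alone, with a median difference of 0.70 (adjusted p = 1.7e-35). The excess held for 5 of 12 ERK feedback inhibitors, with SOCS2 the 1 below, or for 6 and 1 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.00011). DUSP5 differed by 1.22 ± 0.14 and DUSP4 by 1.18 ± 0.17. It held for 8 of 13 RNA decay genes, 8 up and 1 down adjusted over the list alone, with a median of 0.50 (adjusted p = 1.3e-13). Of 11 secreted ligands 7 exceeded, or 8 adjusted over the list alone, with a median of 0.88 (adjusted p = 9.5e-13), CCN2 by 1.44 ± 0.19 and HBEGF by 1.18 ± 0.22. Of 15 cytoskeleton, adhesion and invasion genes 8 exceeded, or 9 adjusted over the list alone, with a median of 0.37 (adjusted p = 1.3e-13), PHLDA1 by 1.39 ± 0.17 and VCL by 0.80 ± 0.08. For CREB and cAMP early genes it was 6 of 9, also adjusted over the list alone, with a median of 0.69 (adjusted p = 8.1e-13). Short-lived regulators had 8 of 17 above, or 9 above and 1 below adjusted over the list alone, with a median of 0.34 (adjusted p = 2.4e-10). Heat shock genes had 2 of 8 above, also adjusted over the list alone, with a median of 0.10 (adjusted p = 0.012). For G2/M genes 1 of 16 was below, or 6 adjusted over the list alone. Their median of −0.16 had an adjusted p = 0.00054, and adjusted p = 0.100 with an estimated correlation. Sterol synthesis genes had 1 of 10 above, or 3 adjusted over the list alone, and a median of 0.18 (adjusted p = 0.012), but adjusted p = 0.15 with an estimated correlation. Hypoxia genes had 2 of 9 above, or 4 above and 1 below adjusted over the list alone, and a median of 0.12 (adjusted p = 0.012), but adjusted p = 0.071 with an estimated correlation. The actin ratio differed between the ligands as given at the start, 0.898 against 0.347. The GAPDH ratio was 0.375 ± 0.114 (SD, n = 28) with HRG and −0.0190 ± 0.0619 (SD, n = 27) with EGF.

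The immediate early score placed these changes on 1 scale per array. Its late mean was 0.25, 0.51, 0.65 and 1.60 at 0.1, 0.5, 1 and 10 nM EGF (SD 0.09, 0.11, 0.08 and 0.01; n = 3, and n = 2 at 10 nM). With HRG it was 0.99, 1.77, 2.04 and 2.41 (SD 0.19, 0.02, 0.06 and 0.07; n = 3). The untreated arrays stood at −0.185 for EGF and −0.699 for HRG. HRG was above EGF in 11 of 11 matched pairs, by 1.07 on average (SD 0.317, exact sign-flip p = 0.000977, the smallest possible). The ERK feedback score was 0.18, 0.23, 0.26 and 0.64 with EGF and 0.37, 0.68, 0.78 and 0.98 with HRG. HRG was higher in 11 of 11 pairs, by 0.377 (SD 0.147, the same p). All pairs shared the early baselines, so they were not independent. Per factor of 10 in dose, the immediate early score rose by 0.674 with EGF (permutation p = 0.00056, n = 11) and 0.688 with HRG (permutation p = 6e-04, n = 12). The score already rose with HRG dose at 5 and 10 min, with early means of −0.30, −0.06, 0.08 and 0.27, against −0.05, −0.05, 0.00 and 0.10 with EGF. Part of the late HRG rise was thus there early. The feedback score rose by 0.226 (permutation p = 0.00116) and 0.299 (permutation p = 0.00042). With both ligands dose followed scan day, and these permutations crossed days. From pairs of doses scanned on the same day, tried after the values were seen, the immediate early slopes were 0.726 and 0.609 and the feedback slopes 0.251 and 0.285. Their exact p was 0.0625 with EGF (n = 5 pairs) and 0.0312 with HRG (n = 6 pairs), in each case the smallest that the pairs can give.

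**Figure D4:**
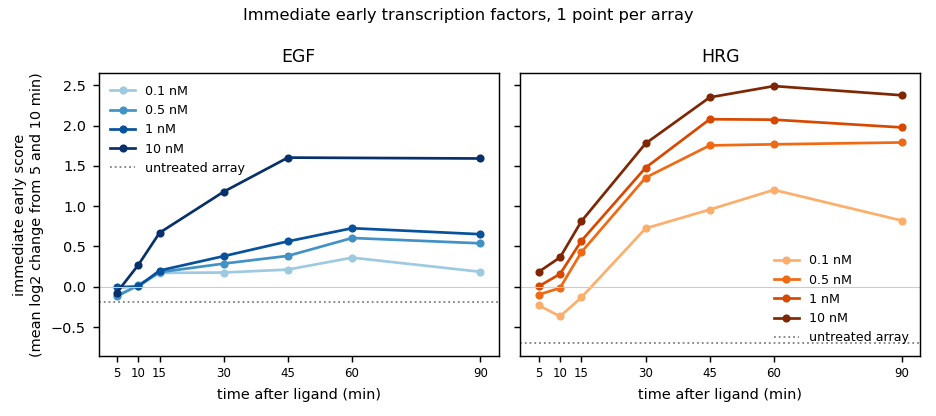
Immediate early score of each array (y axis, mean log2 change of 27 genes from the 5 and 10 min arrays of the same ligand) by time after ligand (x axis, min), 1 line per dose with darker shades for higher doses; the dotted line is the untreated array. At 10 nM the late mean is 1.60 with EGF, whose line passes over the 60 min array that was not analysed here, and 2.41 with HRG.

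Dose dependence gene by gene was measured as the late dose slope, in log2 units per factor of 10 in dose. With EGF the steepest rises were those of EGR4 (2.12 ± 0.18, adjusted p = 5.6e-11), NR4A3 (2.03 ± 0.23, 3.5e-08), NR4A1 (1.57 ± 0.24, 2.6e-05) and EGR3 (1.41 ± 0.14, 2.5e-09). With scan day as a block they were 2.26, 2.10, 1.86 and 1.39, and less the slope at 5 and 10 min 2.05, 1.71, 1.22 and 0.87. The NR4A1 call was lost less the early slope (adjusted p = 0.15) and without probe sets of lower specificity (0.64, 0.051). MAFF (1.16 ± 0.12), CCN1 (1.16 ± 0.12), GEM (1.10 ± 0.15) and CCN2 (1.07 ± 0.13) followed, with adjusted p of 1.9e-06 or less, blocked slopes of 1.15, 1.32, 1.08 and 1.10, and slopes less the early slope of 0.91, 0.85, 0.93 and 1.13. The negative slopes of PRRC1 (−0.68 ± 0.16, adjusted p = 0.0054), the malectin gene MLEC (−0.64 ± 0.11, 0.00022), the splicing factor gene SRRM2 (−0.64 ± 0.16, 0.014) and SPIN1 (−0.63 ± 0.14, 0.0043) passed as well. Less the slope at 5 and 10 min they were −0.07, −0.09, −0.07 and −0.17, with adjusted p from 0.93 to 0.98. A second MLEC probe set read −0.01, and a pair of other SRRM2 probe sets −0.12 and 0.12. By group, 22 of 27 immediate early factors had a positive and 1 a negative slope, or 24 and 1 adjusted over the list alone, with a median of 0.50 (adjusted p = 2.7e-35). Of 11 secreted ligands 7 had a positive and 1 a negative slope, or 8 and 1 adjusted over the list alone, with a median of 0.42 (adjusted p = 5e-10). Of 9 CREB and cAMP early genes 6 had a positive slope, or 7 adjusted over the list alone, with a median of 0.55 (adjusted p = 4.4e-10). ERK feedback inhibitors had 3 of 12 up, or 4 adjusted over the list alone, with a median of 0.19 (adjusted p = 0.00051). RNA decay genes had 5 of 13 up, or 7 up and 1 down adjusted over the list alone, with a median of 0.14 (adjusted p = 3.7e-06). Short-lived regulators had 7 of 17 up, or 9 up and 1 down adjusted over the list alone, with a median of 0.19 (adjusted p = 9.1e-10). Cytoskeleton genes had 3 of 15 up, also adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0095). ErbB receptors and adaptors had 2 of 16 lower at higher dose, also adjusted over the list alone, and a median of −0.07 (adjusted p = 0.010), but adjusted p = 0.097 with an estimated correlation. When scan day was a block 18 immediate early factors had a positive slope, 8 secreted ligands were up and 1 down, and 5 CREB and cAMP early genes, 2 feedback inhibitors, 5 short-lived regulators and 4 cytoskeleton genes were up. RNA decay genes had 4 up and 1 down with the block, and ErbB receptors and adaptors 3 down. In all, 366 genes passed, 196 positive and 170 negative, and 394 with scan day as a block, but only 24 (21 positive, 3 negative) for the late less the early slope. The count was 29 without EGF 10 nM at 90 min, 61 without 10 nM at 45 min, 224 without 0.1 nM at 90 min and 24 with 90 min left out. That setting also lost GEM (0.75, adjusted p = 0.056), PRRC1, MLEC, SRRM2 and SPIN1. The actin ratio moved with EGF dose as given above, and with it as a covariate 414 genes passed (223 positive, 191 negative).

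With HRG the late dose slope was 1.64 ± 0.12 for CCN2 (adjusted p = 6.4e-14), 1.61 ± 0.20 for FOSB (7.1e-08) and 1.49 ± 0.20 for NR4A3 (4.5e-07). It was 1.36 ± 0.16 for EGR4 (adjusted p = 2.6e-08), 1.32 ± 0.10 for ATF3 (1.4e-12) and 1.29 ± 0.10 for CCN1 (1.4e-12). With scan day as a block these were 1.47, 1.81, 1.38, 1.23, 1.29 and 1.31. The RNA helicase gene DHX9 (1.48 ± 0.23, adjusted p = 1.3e-05) and the osmotic stress factor NFAT5 (1.31 ± 0.27, 5e-04) had blocked slopes of 0.27 (0.29) and −0.03 (0.95). Other probe sets read −0.02 and 0.30 for DHX9 and 0.49 for NFAT5. Among the negative slopes, that of PPP1R3C (−0.63 ± 0.06, adjusted p = 1.1e-09) was −0.49 with the block. Those of MAN2A1, a Golgi mannosidase (−0.63 ± 0.13, 0.00057), GUCY1B2 (−0.56 ± 0.11, 0.00039) and the kinase SYK (−0.53 ± 0.17, 0.022) became 0.05 (0.74), −0.37 (0.15) and −0.67 (0.073). Less the early slope, ATF3 kept 1.44 (adjusted p = 3.3e-07) and CCN2 0.83 (0.0062), while FOSB (0.69, 0.22) and EGR4 (0.58, 0.20) did not pass. By group, 24 of 27 immediate early factors had a positive slope, also adjusted over the list alone, and 19 with the block, with a median of 0.59 (adjusted p = 2.8e-43). RNA decay genes had 8 of 13 up, or 9 adjusted over the list alone, with a median of 0.26 (adjusted p = 1.1e-15). Short-lived regulators had 11 of 17 up, also adjusted over the list alone, with a median of 0.28 (adjusted p = 3.6e-17). Cytoskeleton genes had 8 of 15 up, also adjusted over the list alone, with a median of 0.18 (adjusted p = 9.3e-10). CREB and cAMP early genes had 6 of 9 up, or 7 adjusted over the list alone, with a median of 0.66 (adjusted p = 8.9e-13). Of 12 ERK feedback inhibitors 6 were positive and 1 negative, or 7 and 1 adjusted over the list alone, with a median of 0.25 (adjusted p = 1.1e-06). Of 11 secreted ligands 6 were positive and 1 negative, also adjusted over the list alone, with a median of 0.34 (adjusted p = 5.6e-10). Quiescence and FOXO targets passed with 4 up and 1 down of 16, hypoxia genes with 2 of 9 up and heat shock genes with 2 of 8 up, each also adjusted over the list alone. Their medians were 0.01 (adjusted p = 0.0049), 0.04 (0.0051) and 0.05 (0.013). Fitted with scan day as a block, 8 RNA decay genes, 9 short-lived regulators, 7 cytoskeleton genes, 5 CREB and cAMP early genes, 5 feedback inhibitors and 4 secreted ligands had a positive slope. So did 3 quiescence and FOXO targets, 1 hypoxia gene and 2 heat shock genes, and none of these lists had a negative one. In all, 1301 genes passed, 408 positive and 893 negative. With scan day as a block 246 passed (152 and 94), and 239 (97 and 142) for the late less the early slope. The count was 674 without HRG 0.1 nM at 90 min, 792 without 10 nM at 90 min and 103 (64 positive, 39 negative) without all 0.1 nM arrays. RNA quality moved with HRG dose too: the late actin ratio was 0.965, 1.146 and 1.178 at 0.1 nM and 0.713, 0.809 and 0.609 at 10 nM, and the early ratio 1.723 and 1.326 at 0.1 nM. With this ratio as a covariate 1541 genes passed (485 positive, 1056 negative).

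The late dose slopes of the ligands were compared last. Slopes were steeper with HRG for NFAT5 (2.19 ± 0.41, adjusted p = 0.00086), DHX9 (2.12 ± 0.36, 0.00034), SECISBP2L (1.56 ± 0.27, 0.00042) and the RNA-binding protein gene SYNCRIP (1.36 ± 0.21, 0.00011). The block for scan day left 1.09 (adjusted p = 0.0094), 1.06 (0.0045), 0.75 (0.011) and 0.83 (0.0032). For the same difference, other probe sets read 0.91 for NFAT5, −0.14 and 0.53 for DHX9, −0.17 for SECISBP2L, and 0.08, −0.04, −0.07 and 0.02 for SYNCRIP. Less the early slope these differences were 0.04, 0.44, 0.10 and 0.28, with adjusted p from 0.70 to 0.98. With 90 min left out NFAT5 (2.17, adjusted p = 0.071), DHX9 (2.05, 0.069) and SECISBP2L (1.46, 0.071) did not pass. Slopes were lower with HRG for EGR3 (−0.86 ± 0.19, adjusted p = 0.0041), MAN2A1 (−0.82 ± 0.20, 0.0081), the kinase CLK2 (−0.64 ± 0.17, 0.021) and the mucin MUC5B (−0.62 ± 0.18, 0.028). Of these EGR3 passed with scan day as a block (−1.07, 0.0094) and MAN2A1 (−0.17, 0.39), CLK2 (−0.19, 0.69) and MUC5B (−0.33, 0.45) did not. Less the early slope EGR3 (−1.05, adjusted p = 0.075), MAN2A1 (0.08, 0.92), CLK2 (−0.64, 0.24) and MUC5B (−0.65, 0.24) were all lost, as they were with 90 min left out, where EGR3 read −0.92 (0.083). The late EGR3 change went from 1.23 at 0.1 nM to 2.91 at 10 nM EGF, but from 3.36 to 3.07 with HRG. As a list the immediate early factors did not pass, with 5 of 27 steeper and 2 less steep with HRG, or 6 and 4 adjusted over the list alone, and a median of 0.06 (adjusted p = 0.074). Cytoskeleton genes had 2 of 15 steeper, or 6 steeper and 1 less steep adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0053) and RHOB at 0.33 ± 0.05. RNA decay genes had 2 of 13 steeper, or 3 adjusted over the list alone, and a median of 0.10 (adjusted p = 0.0053), but adjusted p = 0.110 with an estimated correlation. Quiescence and FOXO targets had 3 of 16, or 5 adjusted over the list alone, and a median of 0.02 (adjusted p = 0.0053), but adjusted p = 0.058 with an estimated correlation. Short-lived regulators had 3 of 17, or 3 up and 1 down adjusted over the list alone, and a median of 0.09 (adjusted p = 0.013), but adjusted p = 0.270 with an estimated correlation. In the fit with scan day as a block 0 immediate early factors were steeper and 1 less steep with HRG, and 1 cytoskeleton gene, 1 RNA decay gene, 2 quiescence and FOXO targets and 0 short-lived regulators were steeper. In all, 409 genes passed, 183 positive and 226 negative, 136 with scan day as a block (57 and 79) and 21 for the late less the early slope, all negative. The count was 91 without EGF 10 nM at 45 min, 80 positive and 48 negative without 10 nM at 90 min, 269 without 0.1 nM at 90 min and 5 with 90 min left out. The balance of directions turned with all probe sets (565 positive, 372 negative) and without the 0.1 nM (95 and 76), 0.5 nM (114 and 68) or 10 nM arrays (46 and 16).

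The untreated arrays gave the background. Against its untreated array, late EGF arrays differed in 243 genes (116 higher, 127 lower), led by FOS at 2.51 ± 0.35 and EGR4 at 2.17 ± 0.42, and late HRG arrays in 3360 (2033 higher, 1327 lower), led by EGR4 at 6.20 ± 0.41. A single untreated array has no spread of its own, so that these SE and p-values rest on the spread of the treated arrays and take the untreated array to vary as they do. Of the genes that passed for late against early, 44 of 379 with EGF and 563 of 1167 with HRG passed here in the same direction. TXNIP was 1.19 ± 0.15 below its untreated level in late HRG arrays, and NR4A3 was higher in the untreated HRG array, at 7.61 on the log2 scale, than in the early HRG arrays, at 5.47. The untreated HRG array stood apart, with a mean correlation to the other arrays of 0.931 against 0.970 for the untreated EGF array, an actin ratio of 1.52 and the lowest median signal, 106.8. Quantile normalization left 141 genes for EGF (85 higher, 56 lower), which turned the balance of directions, and 3190 for HRG (1695 higher, 1495 lower). Array weights gave 718 for EGF, and the actin ratio as a covariate 132 (87 higher, 45 lower).

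The 2 arms already differed at 5 and 10 min. Between the early HRG and EGF arrays 3448 genes passed, 1573 higher and 1875 lower with HRG, so that levels were not compared between the ligands directly. TFF3, a trefoil peptide, was lower with HRG by −1.98 ± 0.08 and the growth factor BMP7 by −1.98 ± 0.11, while the pregnancy-specific glycoprotein PSG9 was 1.96 ± 0.10 higher; these were named after their values were seen. With scan day as a block 2279 genes passed, and 1314 with the actin ratio as a covariate. Early dose slopes passed in 819 genes with EGF (360 positive, 459 negative) and 116 with HRG (64 and 52), with CEACAM5 (0.79 ± 0.13) and CEACAM6 (0.77 ± 0.12) the steepest positive ones with EGF. The EGF count was 28 and 44 without the 10 nM arrays at 5 and 10 min, and the HRG count 16 and 21 without 0.1 and 10 nM at 5 min and 384 without 10 nM at 10 min. With the actin ratio as a covariate these counts were 625 and 370.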

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

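Of the tests given here, the regression of the late HRG change from the early arrays on that from the untreated array, the values and regroupings within scan days and the values with the early slope taken off were chosen only after the results were seen.

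The effects of the 2 ligands differed by a test of the difference itself. In the late change, HRG minus EGF, 388 genes differed, and 22, 78, 118 and 328 at 30, 45, 60 and 90 min. The named genes with the larger HRG change were NR4A3 (4.05), EGR4 (3.57), FOSB (2.76), ATF3 (2.35), GEM (2.25), MAFF (2.09), NR4A1 (1.80), TRIB1 (1.71), ARC (1.56) and FHL2 (1.52). Those with the lower HRG change were PPP1R3C (−0.78), AOPEP (−0.75), RPAP2 (−0.70), HEY2 (−0.67), PCDHGA8 (−0.65), SOCS2 (−0.61), DHX57 (−0.58), DDIT4 (−0.58), ZKSCAN4 (−0.56) and FRAT2 (−0.55). Among the lists, the median difference was 0.70 for immediate early factors, 0.27 for ERK feedback inhibitors, 0.50 for RNA decay genes, 0.88 for secreted ligands, 0.37 for cytoskeleton genes, 0.69 for CREB and cAMP early genes, 0.10 for heat shock genes and 0.34 for short-lived regulators. The scores differed by 1.07 for the immediate early factors and 0.377 for the feedback inhibitors. The late dose slope differed in 409 genes, among them NFAT5 (2.19), DHX9 (2.12), SECISBP2L (1.56), SYNCRIP (1.36), EGR3 (−0.86), MAN2A1 (−0.82), CLK2 (−0.64) and MUC5B (−0.62). Blocking for scan day left 136 genes that differed, among them NFAT5 (1.09), DHX9 (1.06), SECISBP2L (0.75), SYNCRIP (0.83) and EGR3 (−1.07), whereas MAN2A1 (−0.17), CLK2 (−0.19) and MUC5B (−0.33) were lost. A second probe set of SECISBP2L (−0.17), 1 of 2 others of DHX9 (−0.14) and all 4 others of SYNCRIP (−0.07 to 0.08) lay near 0 or on the other side of it. Less the early slope the differences of NFAT5 (0.04), DHX9 (0.44), SECISBP2L (0.10), SYNCRIP (0.28) and EGR3 (−1.05) did not pass, and only 21 genes, all negative, did. With 90 min left out 5 genes passed. Outside the genes analysed, 1441 probe sets with no or several gene symbols were bright enough to test, and 34 of them passed for EGF (13 higher, 21 lower) and 220 for HRG (91 higher, 129 lower) between late and early arrays. No sample was set against others of its condition, since each condition held 1 array.

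The first pattern weighed was the difference of 3448 genes between the HRG and EGF arrays at 5 and 10 min. A fast response to HRG that grows was argued against, since the median difference in the called direction was 0.31 at 10 min and 0.33 at 5 min, a ratio of 0.92. Of these genes 79.8% differed in the same direction between the untreated arrays, against 69.2% of all genes, which is consistent with a difference between the arms that was there without ligand. Whether RNA quality had a part cannot be told apart from the ligand, because the actin ratio differs between the arms: with that ratio as a covariate 34.7% of the genes still passed. The ligands shared no scan day, so that a day effect stays open too.

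The second was the larger number of genes that passed between late HRG arrays and the untreated HRG array (3360) than between late and early HRG arrays (1167). RNA quality as the whole cause was argued against, since 81.3% still passed with the actin ratio as a covariate. A ligand response that develops after 10 min was also argued against as the whole cause, because the early arrays would then have stood at the untreated level: over these genes, regressing the late against early change on the late against untreated change through the origin gave 0.19 (0.14 to 0.21 without any 1 early or late HRG array). Of the genes, 79.1% also passed between the early HRG arrays and the untreated array. As both comparisons share that 1 array, its own deviation enters both, and this share decides nothing. That array was scanned alone, so that its day, its sample and a change within 5 min cannot be told apart.

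The third was the late HRG dose slope, which follows the scan days because 0.1 and 0.5 nM were scanned on one day and 1 and 10 nM on another. For the 408 positive slopes, regressing the early on the late slope through the origin gave 0.41 (0.35 without HRG 0.1 nM at 10 min to 0.49 without HRG 10 nM at 5 min), and 21.3% of the genes (87) passed with the early slope taken off. For the 893 negative slopes these were 0.17 (0.01 without HRG 10 nM at 10 min to 0.34 without HRG 0.1 nM at 5 min) and 11.2% (100 genes). A step between the days and a dose response that develops after 10 min may both have contributed, and for these genes the tests could not tell them apart. With scan day as a block 136 of the positive and 67 of the negative slopes still passed.

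Whether chance can be excluded was tested by redrawing the groups 100 times, the real grouping included. Time labels were shuffled within each ligand and dose for changes with time, ligands were swapped within the 27 matched pairs for ligand differences, after taking off the early difference where the change was tested, and doses were shuffled within each ligand and time for slopes. The rule was met for the EGF late change (1 of 100 gave as many genes, 379 against at most 5 in the others) and the HRG late change (1 of 100, 1167 against 557). For EGF at single times it was met at 30 min (1 of 100, 16 against 1), 45 min (1 of 100, 48 against 2), 60 min (1 of 100, 51 against 4) and 90 min (1 of 100, 160 against 1). At 15 min 2 of 100 gave as many (1 gene against 1), but a single gene that was lost or joined by others without any 1 of 38 arrays carries little. For HRG the rule was not met at 15 min (7 of 100, 8 genes against 439), and was at 30 min (3 of 100, 79 against 325), 45 min (1 of 100, 326 against 274), 60 min (3 of 100, 524 against 580) and 90 min (1 of 100, 1120 against 347). For the ligand difference it was met in the late change (3 of 100, 388 against 763), at 30 min (1 of 100, 22 against 18), 45 min (3 of 100, 78 against 130), 60 min (2 of 100, 118 against 162) and 90 min (3 of 100, 328 against 394), and for HRG against EGF at 5 and 10 min (1 of 100, 3448 against 1045). For slopes it was met for EGF late (1 of 100, 366 against 5), HRG late (1 of 100, 1301 against 221), their difference (1 of 100, 409 against 174), EGF early (1 of 100, 819 against 108) and HRG early (2 of 100, 116 against 116). These shuffles crossed the scan days, which followed dose, so that a step between the days stays open. Late doses were therefore also swapped only within ligand, time and scan day, with the day as a block, a test added after the results were seen. There the rule was not met for EGF (3 of 32, 394 genes against 402) and was for HRG (2 of 64, 246 against 394) and the difference (3 of 100, 136 against 172). Both regroupings of EGF and the 1 of HRG that called more than the real grouping swapped a single pair of doses at a single time. Regroupings that called several times the real count, as 439 genes against 8 for HRG at 15 min, point to a structure of the samples, which may be no more than the time course, since the shuffles also put late arrays under the earlier times. The cause of these counts was not tested.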

How the results depend on the processing

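The settings chosen only after the results were seen are the early slope taken off, the score slopes within scan day, the actin ratio as a covariate, the fluidics module as a block, single scan days, the untreated HRG array and HRG 0.1 nM at 5 min left out together, and early arrays against the untreated array. A filter at 29 arrays and robust eBayes moved none of the 25 counts by over 1.5 times. The 6 results for the scores kept their direction under each setting run for them, and their side of the threshold except for the EGF slopes within scan day, 0.726 for the immediate early and 0.251 for the feedback score. Their exact p of 0.0625 is the smallest that 5 pairs can give. For the immediate early score the dose slope ran from 0.542 to 0.726 with EGF and from 0.567 to 0.68 with HRG and the ligand difference from 0.811 to 1.05, and for the feedback score these ran from 0.171 to 0.251, 0.266 to 0.295 and 0.255 to 0.368 (highest permutation or exact p 0.0625). No scaling moved the median of all genes by over 0.1. Among named genes, these changed sign: NR4A1 in the ligand difference (−0.09) and SYNCRIP in the slope difference (−0.04) without _x_at and _s_at probe sets; with scan day as a block the HRG slopes of NFAT5 (−0.03) and MAN2A1 (0.05); and with the early slope taken off the HRG slopes of NFAT5 (−0.01) and MAN2A1 (0.05) and the MAN2A1 slope difference (0.08). Signal limits the tests too: 7269 of 11963 genes were above the median of the array in at least 4 arrays. No measure of background was used, and the offset of 32 shrinks changes near it. EGR4 with EGF went the other way: 1.85, but 0.61 with an offset of 1. The balance of directions turned in some settings. Besides those given in the report, dose as a factor gave 621 higher and 736 lower for the HRG late change and 256 and 266 for the ligand difference in it, and EGF late slopes had 187 positive and 217 negative with each ligand alone and 297 and 360 with all probe sets. Leaving out a dose, a time or a class of probe sets tests fewer arrays or genes, which by itself lowers counts; for the other moves the cause was not tested.

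The moved counts were these. Quantile normalization lowered late EGF against its untreated array to 141. The HRG count at 15 min was 4 with an offset of 1 and 5 with no filter. All probe sets, a larger number of tests, gave 5288 for HRG against EGF at 5 and 10 min, 657 for the EGF late slope, 2013 for the HRG late slope, 937 for the slope difference, 234 for the HRG early slope, and 121 and 495 for HRG at 30 and 45 min. Without _x_at and _s_at probe sets, counts were 246 for the EGF late change, 739 for the HRG late change, 112 and 1973 for late EGF and late HRG against their untreated arrays, 243 for the ligand difference in the late change and 1983 for HRG against EGF at 5 and 10 min. Slopes there gave 213 for EGF late, 751 for HRG late, 240 for their difference and 441 for EGF early. Single times there gave 8 and 32 for EGF at 30 and 60 min, 4, 50 and 737 for HRG at 15, 30 and 90 min, and 14, 41 and 217 for the ligand difference at 30, 45 and 90 min. With dose as a factor, EGF at 30 min gave 9, the ligand difference at 30 min 7 and late EGF against its untreated array 433. Dose as a rank gave 190 for the EGF late slope and 261 for the HRG early slope. Each ligand alone gave 48 for the HRG early slope, 9 for EGF at 30 min and 5 for HRG at 15 min. With array weights, the HRG early slope fell to 64, while the EGF late change rose to 956, late EGF against its untreated array to 718, the HRG late slope to 1968, the slope difference to 634 and the EGF early slope to 1277. Single times with array weights rose to 243, 464 and 533 for EGF at 45, 60 and 90 min, 136 and 508 for HRG at 30 and 45 min, and 149, 199 and 503 for the ligand difference at 45, 60 and 90 min. With 5 min as the baseline the EGF late change gave 144. With 30 to 90 min as late, the ligand difference in the late change gave 252, the EGF late slope 640 and the slope difference 644. With 90 min left out, counts were 176 for the EGF late change, 676 for the HRG late change, 217 for the ligand difference, 24 for the EGF late slope, 408 for the HRG late slope and 5 for the slope difference. Scan day as a block gave 2279 for HRG against EGF at 5 and 10 min, 246 for the HRG late slope, 136 for the slope difference, 66 for the HRG early slope, 3 for EGF at 30 min, and 85 and 249 for EGF at 60 and 90 min.

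Leaving out the 0.1 nM arrays gave 97 for the EGF late change, 586 for the HRG late change, 191 for the ligand difference, 2193 for HRG against EGF at 5 and 10 min, 103 for the HRG late slope, 171 for the slope difference and 0 for the HRG early slope. At single times it gave 7, 20, 29 and 64 for EGF at 30, 45, 60 and 90 min, 185 and 290 for HRG at 45 and 60 min, and 71 for the ligand difference at 60 min. Leaving out 0.5 nM gave 89 for the EGF late change, 124 for late EGF against its untreated array, 194 for the ligand difference, 210 for the EGF late slope, 182 for the slope difference, and 340 and 50 for the EGF and HRG early slopes. Its single times gave 5, 18, 16 and 51 for EGF at 30, 45, 60 and 90 min, 4, 200, 346 and 734 for HRG at 15, 45, 60 and 90 min, and 6, 27, 47 and 142 for the ligand difference at 30, 45, 60 and 90 min. Leaving out 1 nM gave 150 for the ligand difference in the late change, 30, 30 and 94 for EGF at 45, 60 and 90 min, 3 and 204 for HRG at 15 and 45 min, and 11, 33, 39 and 185 for the ligand difference at 30, 45, 60 and 90 min. Leaving out 10 nM gave 97 for the EGF late change, 651 for the HRG late change, 243 for the ligand difference, 2250 for HRG against EGF at 5 and 10 min, 8 and 844 for the EGF and HRG late slopes, 62 for the slope difference and 1 for the EGF early slope. It also gave 2, 18 and 47 for EGF at 30, 45 and 90 min, 622 for late EGF against its untreated array and 191 for the HRG early slope. With the early slope taken off, the EGF late slope gave 24, the HRG late slope 239 and their difference 21. Day B alone gave 536 for the HRG late change and day E alone 48 for the EGF late change. Without the untreated HRG array and HRG 0.1 nM at 5 min, the HRG early slope gave 16, and early EGF arrays against the untreated array gave 86. The actin ratio as a covariate gave 132 for late EGF against its untreated array, 1314 for HRG against EGF at 5 and 10 min and 370 for the HRG early slope.

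The count of 1 for EGF at 15 min was 0 with the larger offset, no filter, all probe sets, no _x_at and _s_at probe sets, dose as a factor, no trend, the fluidics module as a block, or without 0.1, 0.5 or 1 nM; 2 with each ligand alone, array weights or the actin ratio as a covariate; 3 with quantile normalization, an offset of 1 or without 10 nM; and 5 with scan day as a block. Leaving out each array in turn, it ran from 0 to 6. It was 0 without EGF 0.1 nM at 5, 15, 30, 45 or 60 min, 0.5 nM at 5, 10, 15, 60 or 90 min, 1 nM at 5, 10, 30, 45 or 60 min or 10 nM at 15 min, or without HRG 0.1 nM at 15, 30 or 60 min, 0.5 nM at 15 or 30 min or 1 nM at 10, 15 or 45 min. It was 2 without EGF 0.1 or 1 nM at 90 min, EGF 10 nM at 5, 30 or 45 min or HRG 10 nM at 45 min, and 3 without HRG 0.1 nM at 45 or 90 min, 0.5 nM at 10 min, 1 nM at 90 min or 10 nM at 5 or 15 min. It was 4 without EGF 0.5 nM at 30 min and 6 without EGF 10 nM at 10 min.

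Leaving out each array in turn, the other EGF counts ran from 3 to 18 at 30 min, 17 to 52 at 45 min, 19 to 65 at 60 min and 58 to 206 at 90 min, and the HRG count from 2 to 10 at 15 min. The ligand difference ran from 47 to 86 at 45 min and from 59 to 134 at 60 min. Late slopes ran from 29 to 474 with EGF, 674 to 1387 with HRG and 91 to 481 for their difference, and early slopes from 28 to 1011 with EGF and 16 to 384 with HRG. The lowest values came without EGF 10 nM at 30 min (3), 45 min (17) and 90 min (58), EGF 0.1 nM at 60 min (19), HRG 1 nM at 15 min (2) and 45 min (47) and EGF 1 nM at 60 min (59). For the slopes they came without EGF 10 nM at 90 min (29), HRG 0.1 nM at 90 min (674), EGF 10 nM at 45 min (91), EGF 10 nM at 5 min (28) and HRG 0.1 nM at 5 min (16), and the highest HRG early slope count, 384, without HRG 10 nM at 10 min. Other arrays that moved these counts by over 1.5 times were EGF 0.1 nM at 10 min (9), EGF 0.1 nM at 30 min and EGF 10 nM at 5 min (10 each) for EGF at 30 min; EGF 0.1 nM for 45 min (22); EGF 0.5 and 1 nM for 60 min (29 and 26); EGF 0.1 and 1 nM for 90 min (82 and 106); HRG 0.1 and 10 nM at 10 min for HRG at 15 min (5 each); and EGF 0.5 nM at 60 min for the ligand difference then (71). For slopes they were EGF 10 nM at 45 min (61) and 0.1 nM at 90 min (224) for EGF late, HRG 10 nM at 90 min (792) for HRG late, EGF 10 nM (80 positive and 48 negative) and 0.1 nM at 90 min (269) for the difference, EGF 10 nM at 10 min (44) for EGF early and HRG 10 nM at 5 min (21) for HRG early. For the remaining counts no single array moved the value by over 1.5 times.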

Other observations

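The gene families, the peak times and the tests of the EGF-lowered genes given here were all chosen after the results were seen. Beyond the lists above, 23 gene families were tested by symbol in 3 contrasts, 69 tests in all, of which 8 passed with the preset correlation and 1 with an estimated one. That one was the solute carriers, membrane transporters, with EGF: 5 of 129 fell and 0 rose, and the median was −0.08 (adjusted p = 0.00011; adjusted p = 0.023 with an estimated correlation). The other 7 were lost with an estimated correlation. Transmembrane protein genes of the TMEM series had a median of −0.09 with EGF (3 of 66 fell, 0.00011; adjusted p = 0.15 with an estimated correlation) and protocadherins −0.16 (0 of 12, 0.023; adjusted p = 0.16 with an estimated correlation), while RNA splicing genes had 0.05 (3 of 46 rose, 0.023; adjusted p = 0.24 with an estimated correlation). Histone genes had −0.11 with HRG (5 of 27 fell and 1 rose, 0.012; adjusted p = 0.36 with an estimated correlation). In the difference HRG minus EGF, interferon-stimulated genes had 0.10 (4 of 15 higher, 0.018; adjusted p = 0.34 with an estimated correlation), solute carriers 0.05 (4 higher and 2 lower of 129, 0.046; adjusted p = 0.34 with an estimated correlation) and respiratory chain genes −0.05 (1 higher and 1 lower of 71, 0.039; adjusted p = 0.63 with an estimated correlation).

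Of the 27 immediate early factors, 14 with EGF and 11 with HRG had their highest mean over doses at 90 min, and 3 with each at 30 min. With HRG, the 3 included FOS and ELF3 (only 0.13). JUN (1.32) and MYC (0.80) peaked at 45 min and JUNB (1.69) and EGR1 (1.40) at 60 min. EGR4 (5.65), NR4A3 (5.66), MAFF (3.70) and FOSL1 (2.82) were highest at 90 min, the last time sampled. The EGF mean at 60 min lacked 10 nM, which may hide peaks. The late immediate early score was 1.77 at 0.5 nM HRG and 1.60 at 10 nM EGF, a difference not tested.

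Of the 147 genes that fell with EGF, 12 had a change with HRG that was higher by a test of the difference: ABTB2, CEACAM6, GFOD1, MDK, MVP, OASL, PDCD11, S100P, SERPINA3, TOR1B, UBBP1 and UBE2D4. CEACAM6 moved by −0.62 ± 0.11 with EGF and −0.11 ± 0.11 with HRG (difference 0.52 ± 0.16, adjusted p = 0.042), SERPINA3 by −0.53 ± 0.06 and −0.11 ± 0.06 (0.42 ± 0.09, 0.002), the calcium-binding protein gene S100P by −0.28 ± 0.05 and 0.02 ± 0.05 (0.31 ± 0.07, 0.0048) and the growth factor midkine, MDK, by −0.28 ± 0.08 and 0.16 ± 0.08 (0.44 ± 0.11, 0.0092). OASL moved by −0.64 at 0.1 nM and −0.36 at 10 nM EGF, while CEACAM6 moved by −0.12 and −1.60 from early arrays that rose with dose (early slope 0.77, late slope −0.03). One hypothesis was that these falls are graded by EGF dose within a scan day: 66.7% of the 147 were lower at 10 than at 1 nM. Another was that HRG shares the falls: 89.8% had a change below 0 with HRG and 8.2% passed for a difference above 0. Both may hold for part of the genes, and neither test could decide, since the genes had been chosen for their fall with EGF.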
